A study of Mus musculus with 4 samples.

How the data were processed

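Total RNA of 4 samples of immortalized mouse embryonic fibroblasts was extracted, amplified and labelled with the Illumina TotalPrep kit and hybridised to Illumina mouse whole-genome expression BeadChips, per the labels' protocols. The cells had a mixed 129/SvJ, C57BL/6 and FVB background. They were grown in 10% fetal bovine serum, and selected with puromycin for 7 days after infection. Groups and replicate numbers were taken from the sample titles, with 2 control samples infected with a control virus and 2 knockout samples infected with a virus expressing Cre.

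The deposited non-normalized table gives, per the file headers, each probe's mean bead intensity on a linear scale, its bead standard error, the number of beads and a detection p-value. The lowest signal of each array lies well above 0, so no background had been subtracted. GenomeStudio 1.1 is named in the submitters' processing notes. The authors' second table holds normalised intensity values on a linear scale. Its 4 columns have medians of 106, rank each array's probes as the raw signals do (Spearman correlation of 1) and agree within 0.573% at each rank, but its values lie up to 30.6% from a quantile normalisation of the 4 raw columns. The method is not given in the sources used here and stays unknown. That table was used only as an alternative, with its lowest value of 44.9 subtracted and 16 added before log2, so it is not set against the alternative with no background correction. The bead standard errors of detected probes were about 4.07%, 3.84%, 4.14% and 4.00% of the signal on the 4 arrays (control 1 and 2, knockout 1 and 2).

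Signals were corrected and normalised with the neqc function of limma 3.58.1 in R 4.3.3, which fits the background by normexp from the detection p-values, adds an offset of 16, applies quantile normalisation and takes log2. The offset shrinks differences of dim probes. Probe names came from a platform annotation table, which can be old. Of 25697 probes, 23978 had 1 gene symbol, 0 had several and 1719 had none. Entrez identifiers matched 23962 of them to RefSeq genes of assembly GRCm38.p6, and 0 symbols changed. The files name no genome build, so no coordinates are given, and that assembly served only for names and for which genes neighbour each other or share a chromosome. Probes with a detection p-value under 0.05 on at least 2 of 4 arrays were kept, 12088 in all, and each named gene was represented by its probe with the highest mean, giving 8356 genes. Of 2173 genes with several tested probes, 5 had probes past the threshold in both directions (Ahnak, Ap2b1, Dpcd, Fadd and Tardbp), and no value is given for them.

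Knockout was compared with control by limma's lmFit and eBayes, with 2 residual degrees of freedom and 3.52 prior ones, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene not above background on either array of a group has only a bound there, computed against the higher of its own signal and the lowest detected signal of each array. The genes named are the NELF subunits, the 10 largest differences in each direction among genes past the threshold that were detected on all 4 arrays and did not overlap between groups, the 3 largest bounds in each direction, and up to 3 members of each list past the threshold, or the smallest p where fewer than 2 passed. Brca2, Ccn2, Thbs1, Timp1, Plk1, Prc1, Ldha, Aldoa, Saa3 and Relb, and the genes of the closing section's gene families, were named after their values were seen.

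The 20 gene lists and 7 marker sets were fixed from textbook knowledge before the data were examined, as were the design and most alternatives. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 20 lists. None of the 5 list calls held with an estimated correlation. That test rests on the 2 residual degrees of freedom and also missed a truly shifted list in the simulation below, where genes varied independently. The estimates were -0.0202 for the histone and -0.0427 for the glycolysis list, under the preset value. They were 0.0254, 0.0671 and 0.133 for the mitosis, matrix and cholesterol lists, above the preset value, so camera may overstate those calls. A miss in the test with an estimated correlation does not show that correlation between genes undoes a list. For the mitosis, matrix and cholesterol lists that limit stays open. Intervals of list medians are 95% bootstrap intervals over 2000 resamples of genes, which treat genes as independent. Alternatives changed the source of the values, the background correction, the scaling, the filter on dim probes, the choice of probe, the variance model, the thresholds, a replicate block, the arrays included and the list test.

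The steps were tested on simulated arrays with the real mean signals, mean backgrounds and fitted variances, but with less background noise than estimated from the arrays. Genes varied independently, and a far smaller share was changed than was called in the data, so the rates below may not hold there. Of 100 genes changed by 2-fold, 88 were called in the right direction, and of 100 changed by 1.5-fold, 21, among 8531 genes tested for this comparison. In the same simulation 5 unchanged genes were called, and 0 of 8510 in one with no change. A list of 15 members shifted by -0.4 on the log2 scale was called by camera and was not called with an estimated correlation, while 0 unchanged lists were called. Plots were drawn with matplotlib 3.10.9.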

Results

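Gene expression was measured in immortalized mouse embryonic fibroblasts, cells grown from an embryo that carried 1 conditional (floxed) and 1 deleted allele of Nelfb. Nelfb, known earlier as Cobra1, encodes a subunit of the negative elongation factor NELF, a protein complex that holds RNA polymerase II in a paused state shortly after initiation. The cells were infected with a control retrovirus or with a retrovirus expressing Cre recombinase, which excises floxed DNA, and RNA was taken at 7 days after infection. The series compares the resulting knockout cells with control cells, in a study concerned with the growth and survival of cells lacking this pausing factor. Of the 4 Illumina BeadChip arrays, 2 were of control cells and 2 of knockout cells. Each array read 25697 probes, with a median of 40 beads per probe. Between 45.1% and 46.6% of the probes gave a signal above the negative controls. The median raw signal was 93.8 and 121 on the control arrays and 93.2 and 96.5 on the knockout arrays. After normalisation the log2 values of the tested genes correlated with r = 0.9953 between the control arrays and 0.9967 between the knockout arrays, and with 0.9781 to 0.9798 between arrays of different groups, where r runs across genes, which are not independent replicates. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value below.

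Nelfb transcript was the targeted product and was measured first. Its normalised log2 signal was 7.84 and 7.96 on the control arrays and 5.09 and 5.01 on the knockout arrays, where neither signal was above background (detection p-values of 0.206 and 0.257). Nelfb was at least 4.83-fold lower in the knockout cells (limma adjusted p = 0.000421). These values are from probe ILMN_2655803. A second Nelfb probe, ILMN_2873174, was likewise not above background on either knockout array (detection p-values of 0.174 and 0.207) and was at least 4.46-fold lower. The sources used here do not say which exons Cre removed or where these probes lie. The other NELF subunits gave log2 differences of -0.02 ± 0.08 (SE, 2 arrays per group) for Nelfa (adjusted p = 0.877), 0.15 ± 0.11 for Nelfcd (0.341) and 0.09 ± 0.08 for Nelfe (0.471), none past the threshold. Among 11 measured NELF and pause-release factors, 1 rose and 2 fell, the same counts when adjusted over the list alone. Besides Nelfb these were Hexim1, an inhibitor of the elongation kinase P-TEFb, at -0.41 ± 0.08 (adjusted p = 0.015), and the elongation factor Supt6 at 0.40 ± 0.08 (adjusted p = 0.02). Both lost their call in 3 of the 4 fits that left out an array, with adjusted p of up to 0.0981 for Hexim1 and 0.115 for Supt6, each highest without knockout replicate 1. The list as a group did not differ from the other genes (camera adjusted p = 0.795).

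**Figure D1:**
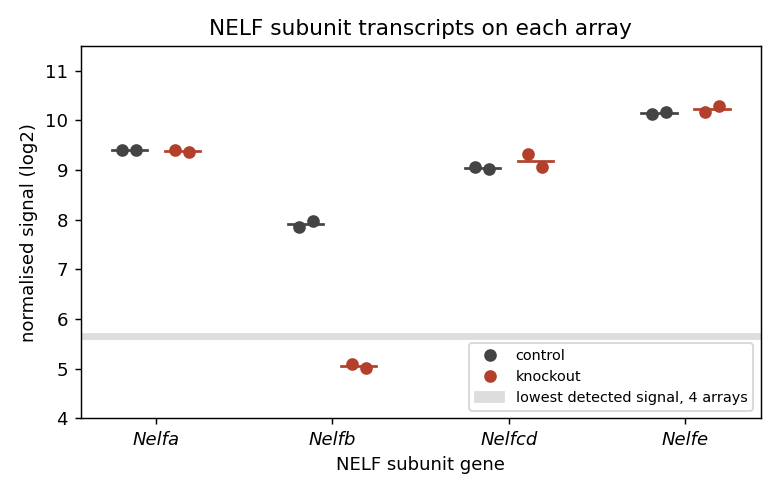
Normalised log2 signal (vertical axis) of the NELF subunit genes (horizontal axis) on each control array (dark points) and knockout array (red points), with short lines at the group means and a grey band over the lowest detected signal of the 4 arrays. Nelfb lies at 7.84 and 7.96 in control and, below the band, at 5.09 and 5.01 in knockout cells, while the group means of Nelfa, Nelfcd and Nelfe differed by 0.15 or less.

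Among genes detected on all 4 arrays, the largest increases in the knockout cells were those of Sdcbp2, Whrn and members of the proliferin family, and the largest decreases were those of Cxcl5, Ifi27l2a, Serping1 and Sfrp2. Sdcbp2, which encodes the scaffold protein syntenin-2, rose by 3.65 ± 0.14 on the log2 scale (SE, 2 arrays per group; adjusted p = 0.00046). Its control signals were 5.71 and 6.08, where the lowest detected signals of those arrays were 5.70 and 5.59. The control side therefore lay near background, and the size of this rise is uncertain. Whrn, encoding the scaffold protein whirlin, rose by 2.36 ± 0.09. The prolactin-related genes Prl2c1, Prl2c4 and Prl2c3 rose by 2.48 ± 0.10, 2.41 ± 0.13 and 2.21 ± 0.12, but these near-identical paralogs may share signal, so which copy changed is uncertain. The linker histone gene H1f2 rose by 1.90 ± 0.08, Adssl1, an enzyme of purine nucleotide synthesis, by 1.62 ± 0.08, Pbld2 by 1.61 ± 0.09, Csrnp1 by 1.61 ± 0.08 and Tnfaip3, which encodes the NF-kB inhibitor A20, by 1.59 ± 0.08. Cxcl5, a chemokine that attracts neutrophils, fell by 2.80 ± 0.12 (adjusted p = 0.000562) and its relative Cxcl1 fell by 1.93 ± 0.11. Ifi27l2a, an interferon-induced gene, fell by 2.40 ± 0.08, and Serping1, encoding the complement C1 inhibitor, by 2.37 ± 0.08. The Wnt antagonist gene Sfrp2 fell by 2.16 ± 0.11, the carbonyl reductase gene Cbr2 fell by 2.04 ± 0.09, and the transporter gene Abcc3 fell by 2.02 ± 0.10. Mme, encoding the peptidase neprilysin, fell by 1.88 ± 0.07, the small proteoglycan gene Ogn by 1.83 ± 0.09 and the collagen gene Col3a1 by 1.82 ± 0.09. Lack of overlap between the groups was a condition for naming these genes. The limma adjusted p of the 20 genes ran from 0.000421 to 0.000938. Control signals of Prl2c1, Whrn and Pbld2 and knockout signals of Sfrp2 and Col3a1 ran from 6.00 to 6.24. These too lay near the lowest detected signals of the arrays, so the sizes of those differences are uncertain as well.

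Some transcripts were above background in 1 group only. Akr1c18, a hydroxysteroid dehydrogenase that inactivates progesterone, was at least 4.72-fold higher in the knockout cells (adjusted p = 0.000562), P2rx7, an ATP-gated ion channel, at least 4.21-fold higher (0.000421), and Serpinb9g at least 3.92-fold higher (0.000421). Apart from Nelfb, the genes not detected on either knockout array with the largest bounds were Angptl7, at least 4.13-fold lower (adjusted p = 0.000801), and Mrgprf, at least 3.22-fold lower (0.00046). Mrgprf belongs to a chromosome whose genes lay lower as a whole, with a median log2 difference of -0.168 over 626 tested genes. These bounds set the bright group's mean against the lowest detected signal of the arrays of the dim group.

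Of 8356 genes tested, 1263 were higher and 1175 lower in the knockout cells (limma, adjusted p under 0.05), which is 29.2% of the genes, with 51.8% of the calls higher. With genes not above background in 1 group taken at their bound, a difference of at least 1.5-fold was present in 423 of the higher and 388 of the lower genes, and one of at least 4-fold in 10 and 8. The arrays of the 2 groups did not overlap for 5714 genes, or 68.4%, against the 33.3% that chance gives for 2 arrays against 2. Scaling the arrays to equal medians in place of quantiles gave 332 higher and 632 lower genes, so that 34.4% of the calls were higher. Those medians were taken over all probes, most of them not above background. The median difference of all tested genes was then -0.0753, against 0.00938 with quantiles. The tilt toward lower genes thus goes with a shift of all tested genes. Leaving out an array gave 790 higher and 728 lower genes without control replicate 1, 729 and 668 without control replicate 2, 319 and 291 without knockout replicate 1, and 335 and 320 without knockout replicate 2.

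**Figure D2:**
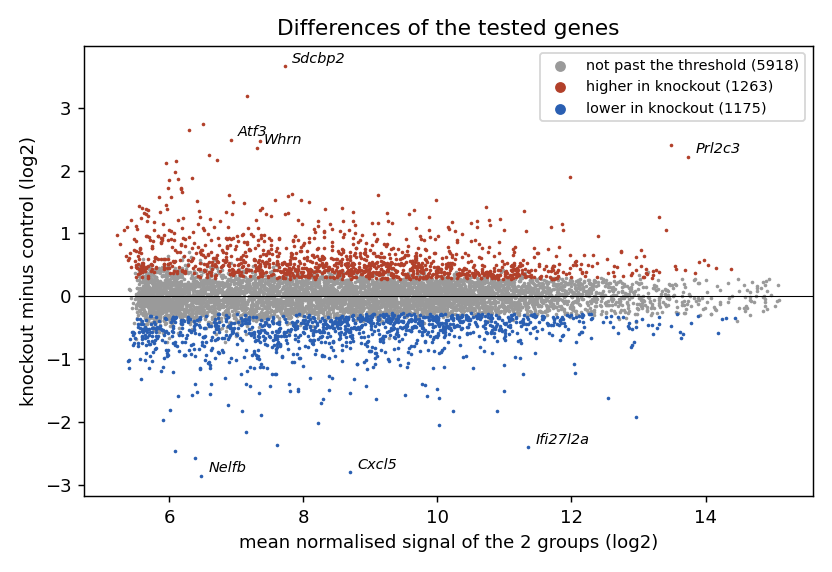
Knockout minus control difference (vertical axis, log2) against the mean normalised signal of the 2 groups (horizontal axis, log2), with 1 point per tested gene; red points are the 1263 genes higher and blue points the 1175 genes lower in knockout cells at an adjusted p under 0.05, and grey points are the rest. Among genes detected on all 4 arrays, Sdcbp2 lies highest, at 3.65, and Cxcl5 lowest, at -2.80. The control signals of Sdcbp2 lay near background, so its height is an uncertain size. Points of genes not above background in 1 group, Nelfb among them, stand at differences to a signal below background, so their height is not a measured size.

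Transcripts of the replication-dependent histone genes, which package newly copied DNA and mostly lack poly(A) tails, were mostly higher in the knockout cells. Of 44 measured genes, 27 rose and 3 fell, or 28 and 7 when adjusted over the list alone, with a median log2 difference of 0.69, or 0.50 with undetected genes at their bounds. All 11 measured H2B genes rose, as did 7 of 10 H4 genes, 4 of 9 H3 genes, 4 of 13 H2A genes and the H1 gene. H2bc6 rose by 2.17 ± 0.08 (adjusted p = 0.000421) and was detected on 1 of 2 control arrays, H1f2 rose by 1.90 ± 0.08, and H3c7 was at least 2.67-fold higher. Members of 1 family are close copies whose probes can share signal, so the count of separate genes is uncertain. The H2A genes as a family had a median of -0.152, and 1 of them and 2 H3 genes fell. Against the other genes the list was higher by camera (adjusted p = 4.6e-06; adjusted p = 0.39 with an estimated correlation). Of 6 replication-independent histone genes, H2aj (0.49 ± 0.11) and H1f10 (0.43 ± 0.09) rose, also when adjusted over the list alone, with adjusted p of 0.0291 and 0.0235. Without knockout replicate 1 the p of H2aj was 0.143, without knockout replicate 2 that of H1f10 was 0.13, and these were the highest of 3 and 4 such losses; the list had a camera adjusted p of 0.406.

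Cholesterol synthesis genes were lower. Of 15 measured, 11 fell and 0 rose, or 13 and 0 when adjusted over the list alone, and the median was -0.41, or -0.37 with undetected genes at their bounds. Mvd, which makes isopentenyl pyrophosphate from mevalonate pyrophosphate, fell by 0.98 ± 0.11, Hmgcs1, the HMG-CoA synthase of the pathway, by 0.81 ± 0.11, and Lss, the lanosterol synthase, by 0.72 ± 0.08. Hmgcs1 had an adjusted p of 0.00618, which became 0.051 without knockout replicate 1 and 0.0503 without knockout replicate 2. The list was lower than the other genes by camera (adjusted p = 4.6e-06; adjusted p = 0.39 with an estimated correlation).

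Genes of the extracellular matrix and of fibroblasts were mostly lower, with 14 of 25 lower and 3 higher, or 15 and 5 when adjusted over the list alone. The fibrillar collagen genes Col3a1 and Col1a1 fell by 1.82 ± 0.09 and 1.24 ± 0.11, and Col6a2, of the microfibrillar collagen VI, fell by 1.42 ± 0.10. The list's median was -0.37, below the other genes by camera (adjusted p = 0.00103; adjusted p = 0.39 with an estimated correlation). The genes that rose were the matricellular genes Ccn2 (1.06 on the log2 scale) and Thbs1 (2.14-fold) and the protease inhibitor gene Timp1 (0.43).

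Mitosis and G2/M genes were lower, with 7 of 18 lower and 0 higher, or 10 and 0 when adjusted over the list alone, and a median of -0.31. Mad2l1 and Bub1b, of the spindle checkpoint, fell by 0.69 ± 0.09 and 0.50 ± 0.09, and Cdc20, the activator of the anaphase-promoting complex, fell by 0.63 ± 0.08. Plk1 and Prc1, 2 of the genes that fell, belong to the chromosome that lay lower as a whole, and without its genes the list's median was -0.27 and its camera adjusted p 0.00014. With all genes the list was below the others by camera (adjusted p = 6.55e-05; adjusted p = 0.39 with an estimated correlation). Single calls were near the threshold with an array left out, at an adjusted p of 0.0502 for Mad2l1 without knockout replicate 2, 0.051 for Cdc20 without knockout replicate 1, and for Bub1b 0.0548 without control replicate 2, 0.0907 without knockout replicate 1 and 0.0549 without knockout replicate 2. The DNA replication and S phase genes did not move as a group, with 1 of 24 higher and 3 lower, 1 and 0 when adjusted over the list alone, a median of -0.04 and a camera adjusted p of 0.795. The cell cycle transcription factor gene E2f1 rose by 0.59 ± 0.08, and Dbf4 and Rrm1, which activate origins and make deoxynucleotides, fell by 0.41 ± 0.10 and 0.49 ± 0.12, Rrm1 being on that same chromosome. Dbf4 and Rrm1 lost their call without any 1 of the 4 arrays, with adjusted p from 0.0747 to 0.189 and from 0.0506 to 0.147, and E2f1 lost it without knockout replicate 1 (0.0508) or 2 (0.0558).

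Glycolysis and hypoxia genes included 8 lower and 1 higher of 18, the same when adjusted over the list alone. P4ha2, a collagen prolyl hydroxylase, fell by 0.85 ± 0.09 and Adm, encoding the peptide adrenomedullin, by 0.69 ± 0.11, whereas the growth factor gene Vegfa rose by 1.04 ± 0.09. The median was -0.19 and the list was lower by camera (adjusted p = 0.0347; adjusted p = 0.39 with an estimated correlation). Adm, Ldha and Aldoa belong to the chromosome that lay lower as a whole, and without its genes the adjusted p was 0.134. The call also ended without control replicate 2 (0.114), without knockout replicate 1 (0.0652), with equal array medians (0.112) and with a detection p-value under 0.01 required on all 4 arrays (0.059), in a range of 0.0171 to 0.39 over the 14 alternatives that compare a list with other genes, and that of Adm without control replicate 1 (0.0526) or knockout replicate 2 (0.0571).

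**Figure D3:**
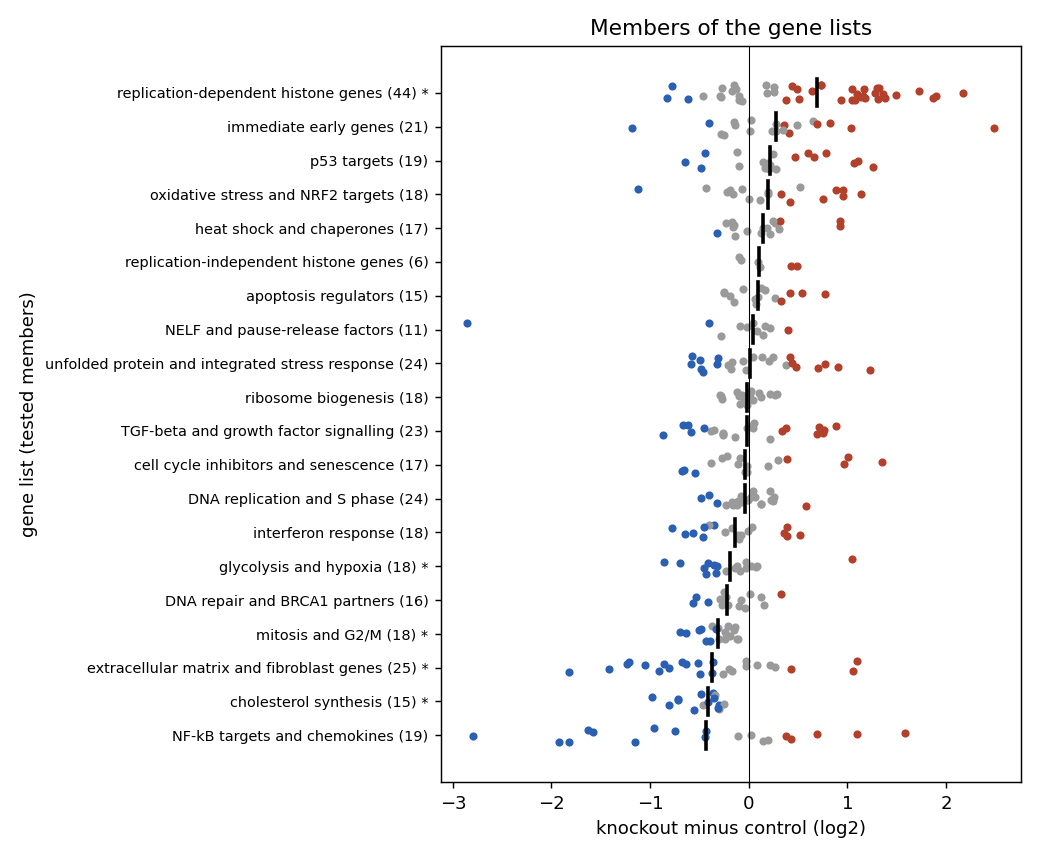
Knockout minus control difference (horizontal axis, log2) of each tested member of the 20 gene lists (vertical axis, number of tested members in brackets, * for a camera adjusted p under 0.05). Red and blue points are genes higher and lower at an adjusted p under 0.05, grey points are the rest, and black bars are medians, which run from -0.43 for NF-kB targets and chemokines to 0.69 for replication-dependent histone genes.

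NF-kB targets and chemokines went both ways, with 10 of 19 lower and 5 higher, the same when adjusted over the list alone. Cxcl5 and Cxcl1 fell as above, Lcn2, which encodes an iron-binding secreted protein, fell by 1.82 ± 0.15, and Tnfaip3 rose by 1.59 ± 0.08. The median was -0.43, but the list did not pass against the other genes (camera adjusted p = 0.0863). It passed in 5 of the 14 alternatives that compare a list with other genes (range 1.11e-05, with equal array medians, to 0.581), including the fit without knockout replicate 2 (0.0303). Without Saa3 and Relb, which belong to the chromosome that lay lower, the median was -0.11 and the camera adjusted p 0.175. Relb was itself the median member at -0.43, and the next member was Nfkbia at -0.11. The move of the median therefore reflects a gap between neighbouring members. Cxcl5, Cxcl1 and Lcn2, which fell, and Tnfaip3, which rose, remained in the list. Interferon response genes had 6 of 18 lower and 4 higher, the same when adjusted over the list alone, with Isg15, a ubiquitin-like modifier, at -0.77 ± 0.11 (adjusted p = 0.00824, and 0.0631 without knockout replicate 1) and a camera adjusted p of 0.206. Without control replicate 1 the list's median moved from -0.14 to -0.28 and it passed (0.036), the only pass in 14 alternatives that range up to 0.698.

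Stress and death genes did not pass as groups in the main comparison, although single members changed. Of 19 p53 targets, 7 rose and 3 fell, or 8 and 3 when adjusted over the list alone. Pmaip1, encoding the death promoter NOXA, rose by 1.26 ± 0.15, Mdm2, which encodes the ligase that degrades p53, by 1.11 ± 0.10 and the growth arrest gene Gadd45a by 1.06 ± 0.10. The p53 list did not pass, with a camera adjusted p of 0.0513, but passed in 8 of the 14 alternatives that compare a list with other genes (range 0.0144 to 0.39), among them the fits without control replicate 1 (0.0243) and without knockout replicate 2 (0.0429). Of 15 apoptosis regulators, 4 rose and 0 fell, the same when adjusted over the list alone (camera adjusted p of the list 0.406). Bcl2l11, which encodes the death promoter BIM, rose by 0.77 ± 0.11, and Bcl2l1, which encodes the survival protein BCL-XL, by 0.54 ± 0.08. The call of Bcl2l1 ended with equal array medians (adjusted p = 0.196) and with either knockout array left out. Of 21 immediate early genes, 6 rose and 2 fell, or 12 and 4 when adjusted over the list alone. The stress-induced transcription factor gene Atf3 rose by 2.49 ± 0.18, having been detected on 1 of 2 control arrays, Fosl1 rose by 1.04 ± 0.08 and Egr2 fell by 1.18 ± 0.08 (camera adjusted p of the list 0.0956, and under 0.05 in 4 of 14 alternatives, with a range of 0.0144 to 0.392). Of 18 oxidative stress and NRF2 targets, 7 rose and 1 fell, the same when adjusted over the list alone. Nqo1, a quinone reductase, rose by 1.14 ± 0.08 and the glutathione transferase gene Gsta4 by 0.96 ± 0.11, while its relative Gstm2 fell by 1.12 ± 0.08 (camera adjusted p of the list 0.141, and 0.0445 with no filter on dim probes, in a range up to 0.51). Of 24 genes of the unfolded protein and integrated stress response, 7 rose and 7 fell, the same when adjusted over the list alone, with a camera adjusted p of 0.795. Chac1, which degrades glutathione, rose by 1.23 ± 0.08, the chaperone gene Dnajb9 by 0.90 ± 0.09 and Ppp1r15a, on the chromosome that lay lower, by 0.77 ± 0.08. Of 17 heat shock and chaperone genes, 3 rose and 1 fell, the same when adjusted over the list alone, with Hspa1a at 0.93 ± 0.10 and Hspb1 at 0.92 ± 0.13 (camera adjusted p of the list 0.424).

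Growth-related lists did not pass either. Of 17 cell cycle inhibitors and senescence genes, 4 rose and 3 fell, or 5 and 4 when adjusted over the list alone (camera adjusted p = 0.827). Cdkn1c, which encodes the kinase inhibitor p57 and is on that chromosome too, rose by 1.35 ± 0.08 and the transcription factor gene Klf9 by 0.96 ± 0.09. Of 23 TGF-beta and growth factor signalling genes, 7 rose and 5 fell, or 7 and 9 when adjusted over the list alone (camera adjusted p = 0.795). Id4, which blocks differentiation factors, rose by 0.88 ± 0.10. Bmp4 fell by 0.87 ± 0.15 (adjusted p = 0.0114, and 0.0781 without knockout replicate 1). Of 16 DNA repair genes, 1 rose and 3 fell, the same when adjusted over the list alone (camera adjusted p = 0.0682). Lig1, Fanci and Blm belong to the chromosome that lay lower, and without its genes the list's camera adjusted p was 0.154. The list passed in 2 of 14 alternatives, without control replicate 1 (0.0429) and with no filter on dim probes (0.0445), in a range up to 0.39. The checkpoint kinase gene Chek1 was at least 1.30-fold lower (adjusted p = 0.0117), and Rad54l and Rpa2 fell by 0.54 ± 0.11 and 0.41 ± 0.09, while Brca2 rose by 0.33. Chek1 lost its call without knockout replicate 1 (0.0671) or 2 (0.0807), Rad54l without control replicate 1 (0.0671) or knockout replicate 1 (0.12) or 2 (0.07), and Rpa2 without any 1 of the 4 arrays (0.0502 to 0.139). None of 18 ribosome biogenesis genes passed, and 0 passed when adjusted over the list alone. The smallest p of that list were those of Fbl, on the chromosome that lay lower, at -0.28 ± 0.08 (adjusted p = 0.0528), and Nop56, at 0.27 ± 0.08 (0.0596). Under alternative settings Fbl passed in 5 of 12 and Nop56 in 5 of 13. The list's camera adjusted p was 0.795.

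Most markers of other cell types were detected on no array. Among these were Adipoq and Fabp4 of adipocytes, Acan and Sp7 of cartilage and bone, Tubb3 and Snap25 of neural cells, Cdh1 of epithelium and Myod1 of muscle. Only 8 passed the detection filter and were tested. Of these, 4 (Sox9, Col2a1, Map2 and Pparg) had group means well above the detection floor, between 7.64 and 9.34 on the log2 scale. No macrophage and blood marker was detected on any array, and of the endothelial markers only Tek was, on 1 array. Col2a1, a cartilage collagen, fell by 0.52 ± 0.08 (adjusted p = 0.00986) and Map2, a neuronal microtubule protein gene, by 0.44 ± 0.09 (0.0227), each detected on all 4 arrays. Col2a1 lost its call without knockout replicate 1 (0.0799) or 2 (0.0663), and Map2 without any 1 of the 4 arrays (0.0632 to 0.135). Sox9 (0.18, adjusted p = 0.13), Pparg (0.03, 0.819), Krt8 (-0.04, 0.869), Krt19 (-0.43, 0.298), Dcx (-0.30, 0.361) and Myog (0.05, 0.906) did not pass.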

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

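The tests of S phase against the histone and mitosis lists, and those on a single chromosome, were chosen after the results were seen.

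Probes without a gene name were left out of the comparison above, and 233 of the 713 that passed the detection filter differed between knockout and control, 119 higher and 114 lower. The largest named by identifier were ILMN_2742861 at -1.99 and ILMN_2906728 at -1.93, and, in the other direction, ILMN_2660233 at 1.58 and ILMN_1227282, which was not above background in control cells and whose measured log2 means were 4.84 and 6.29.

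Replication-dependent histone transcripts were higher in knockout cells, with a list median of 0.687 (bootstrap interval 0.254 to 1.09). More cells in S phase could be expected to raise the S phase list too, but its median was -0.0423 (-0.124 to 0.0665). The lists need not follow S phase content equally, so a modest rise in S phase cells stays open. With equal array medians the list's median lay 0.669 above that of all genes (0.226 to 1.12), which argues against the quantile step as the source. A constant shift of an array cancels in this difference, so it was not tested. Members of 5 families among the genes that rose argue against signal shared within 1 histone family. These transcripts normally end without a poly(A) tail, so a candidate explanation is that loss of Nelfb left more of them with a tail that the labelling could copy. The arrays cannot separate that from more histone RNA in total, and it was not tested.

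Mitosis and G2/M transcripts were lower, with a median of -0.308 (-0.402 to -0.2). If fewer cells were cycling the S phase list should fall too. Its interval, -0.124 to 0.0665, lay above the upper bound of the mitosis list, so it did not fall by as much. That interval includes a smaller fall, and the lists need not follow cycling equally, so fewer cycling cells are not excluded. With equal array medians the mitosis list lay -0.331 from the median of all genes (-0.423 to -0.223), which argues against the quantile step as the cause. A constant shift of an array cancels in that difference and was not tested. A slower passage through some phases or direct effects on these genes stay open and were not tested.

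The genes of 1 of 20 chromosomes, which carries Igf1r, Ccnd1, Plk1 and Cdkn1c in assembly GRCm38.p6, were lower as a whole, with a median of -0.168 over 626 genes. The medians of the other chromosomes ran from -0.0577 to 0.0694. The lowest of 10000 shuffles matched on expression was -0.0487 (permutation p = 1e-04, the smallest they can give, and 0.002 adjusted over 20 chromosomes, 6 of which passed). With equal array medians the chromosome lay -0.171 from all genes (-0.201 to -0.141), which argues against the quantile step as the source. A constant shift of an array cancels in that difference and was not tested. A lower copy number of this chromosome in the knockout cells is a candidate explanation that stays open: all 25 windows of 25 consecutive genes had a median below that of all genes, but 845 of 1000 shuffled orders of the same genes gave as many, so the windows decide nothing. Over all chromosomes, differences of neighbouring genes correlated with rho = 0.0852 (0.0634 to 0.107; highest of 1000 shuffled orders 0.0337), which straddles the 0.1 set beforehand and leaves copy number open as a wider cause. Outside that chromosome rho was 0.0666 (0.0439 to 0.0894), below 0.1 but above the highest shuffled 0.039. The limit of 0.1 was not calibrated, and leaving out a chromosome that lay lower as a whole moved rho only from 0.0852 to 0.0666. Copy number as a cause of differences on the other chromosomes therefore stays open. Effects of Cre itself cannot be told apart from loss of Nelfb, since 0 arrays are of cells with Cre and an intact Nelfb, and a difference between infected populations that arose by chance stays open as well.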

How the results depend on the processing

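The restriction to list members detected on all 4 arrays and the omission of 1 chromosome were chosen after seeing the data. Nelfb stayed lower and past the threshold wherever it was tested, and its bound ran from at least 2.68-fold with no background correction to at least 5.04-fold without control replicate 1. Counts of higher and lower genes were 332 and 632 with equal array medians, 454 and 424 with a fitted fold of at least 1.5 (423 and 388 with genes below background at their bound), and 447 and 430 with an adjusted p under 0.01. With 1 array left out they ran from 319 to 790 and from 291 to 728, with fewer residual degrees of freedom and the lone array assumed to vary like the other group. They stayed within 1.5 times under the remaining settings, at 1743 and 1579 with a trended, robust variance and 1018 and 950 with no filter on dim probes. The titles number the replicates alike in both groups, but deviations of same-numbered arrays correlated at only 0.0643, so the numbers are not taken as pairs; the replicate block gave 1226 and 1129 genes and 6 lists. The 5 list calls became 8 with normexp without detection p-values, 8 with no background correction, 9 with no filter, 0 with an estimated correlation and 13 with fry, which does not compare a list with other genes, and ran from 4 to 8 with 1 array left out. Without the genes of that chromosome 1222 genes were higher, 1013 lower and 4 lists called. The cause of these differences was not tested. Of the 2438 called genes, 1 turned direction with no filter and 5 with every probe kept, where another probe stood for the gene. Equal array medians ended calls including those of Hexim1, Supt6, E2f1, Dbf4, Rpa2, H2aj, H1f10, Map2, Brca2, Timp1, Plk1, Prc1, Ldha, Aldoa, Relb, Col7a1 and all of Lsm2 to Lsm8 but Lsm4, and no filter those of Rrm1, Dbf4 and H2aj. Nelfb has no value where detection on all 4 arrays at p under 0.01 is required, since it is below background in knockout cells. Lists were not run with every probe, the trended variance or the changed gene thresholds, and the slide block was not run, as no slide is given. Signal over background limits genes near the detection floor, log2 5.59 to 5.70.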

Other observations

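The tests in this part were chosen after the results were seen. Grouping genes by the root of their symbol gave 120 families of at least 8 tested members, of which 2 passed camera after adjustment. All 7 of Lsm2 to Lsm8, whose products form the ring that binds U6 RNA in the spliceosome, fell in the knockout cells, by 0.36 to 0.49 on the log2 scale, with Lsm4 at -0.49 ± 0.08 and Lsm3 at -0.44 ± 0.08. The other measured members, Lsm10, Lsm12 and Lsm14a, gave -0.05, -0.19 and -0.22 and did not pass. The family's median over 10 genes was -0.401 (camera adjusted p = 0.00748; adjusted p = 0.994 with an estimated correlation), and with equal array medians the family's median lay -0.415 from that of all genes, although only Lsm4 passed by itself.

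Collagen genes were the other family, with 12 of 19 lower and 2 higher and a median of -0.476 (camera adjusted p = 0.00748; adjusted p = 0.994 with an estimated correlation), which overlaps the matrix list. With equal array medians 9 were lower and 1 higher, and the median lay -0.485 from that of all genes. Col6a1 and Col5a2 fell by 1.21 ± 0.08 and 1.05 ± 0.09, while Col7a1 rose by 0.40 ± 0.07, a call that ended with equal array medians (adjusted p = 0.444). Col17a1, not above background in control cells, was the other gene that rose. Large ribosomal protein genes, 9 of 32 lower and 0 higher, did not pass (camera adjusted p = 0.0607).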
